A study of Mus musculus with 6 samples.

How the data were processed

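Bulk RNA sequencing was compared between locus coeruleus punches of 3 WT and 3 5xFAD libraries, grouped by the sample titles. Per the labels' protocols, slices were cut on a vibratome, the nucleus was punched out and frozen, RNA was extracted with TRIzol, and poly-A selected libraries were made with a TruSeq RNA kit and sequenced on an Illumina NovaSeq instrument. The submitters' processing notes name STAR, RSEM, DESeq2 and the mouse build mm39. The counting strand and annotation release are not given in the sources used here, so counts of overlapping and antisense genes are uncertain. The labels number the libraries but do not say that each number is a separate animal, give no batch, age or sex, and pair no libraries. The p-values therefore measure only the spread between these samples, part of which may be technical. Each library's column name carries its own lane-like suffix, whose meaning the labels do not give. If the suffixes mark lanes, each library had its own and the genotypes share none. A lane effect then cannot be told apart from its library, nor one that follows the groups from genotype.

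The deposited table holds 56923 genes in 6 library columns, of which 28324 were above 0 in any library. It is named as TPM, yet the columns total 1.71e+07 to 1.80e+07 and differ in their totals, as TPM columns do not. The values are a signal made by the authors, gene counts divided by 1 size factor per library: 100% of the values in each column were whole multiples of 1 step (tolerance 0.001). Size factors by the median-of-ratios method, recomputed over the 19176 genes above 0 in all libraries, differed from the steps by at most 1.33e-15. The size factors were 1.08, 1.16 and 0.979 in WT and 0.865, 0.962 and 1.00 in 5xFAD. The same deposited table gives the authors' log2 fold change with its standard error on the log2 scale, a test score that equals their ratio, and the authors' unadjusted and adjusted p-value for each gene, per the file headers. By comparison with the library columns, the authors' log2 fold change is WT over 5xFAD, and its sign was turned where it is printed. DESeq2 rerun on the recovered reads differed from the deposited values by at most 0.000105 in log2 fold change and 2.18e-05 in p over 28317 genes. Gene symbols were taken from a separate reference of gene names, matched by identifier without its version, which paired 52073 of the identifiers (91.5%) with a symbol. The order of genes along the chromosomes came from GENCODE M21 (GRCm38), which is not the authors' build, so no positions are given.

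The tests, the gene lists, the rule for naming genes and the other settings to try were fixed before the data were examined, and assumed TPM with a floor of 1. As the unit was normalized counts, the floor became a normalized count of at least 10 in at least 3 of the 6 libraries, which left 16411 genes. Values were tested as log2(normalized count + 1) with limma 3.58.1 (R 4.3.3), with a variance trend and robust moderation, and the p-values were adjusted by the Benjamini-Hochberg method over all tested genes at 0.05. The fold changes of low genes are understated on this scale. Of the 39 gene lists, 37 were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists with at least 5 measured members. The other 2 lists, the transgene check and the sex-linked check, were read gene by gene. Camera was repeated with the correlation estimated per list, and fry, which tests whether the genes of a list move one way without comparing them with other genes, was run beside it. The mean log2 value of each list per library was compared between groups with a two-sided exact permutation test, whose smallest p for 3 against 3 is 0.1. Principal components were computed in R 4.3.3, and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

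The rule for the genes named took App, Thy1, Mapt and the sex-linked genes, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, filled up by smallest unadjusted p, and from each list up to 4 members with the smallest p and up to 3 with the highest mean. Unnamed gene models were passed over. Neighbours of Mme and genes under the filter were named after their values were seen. Some genes that the rule names are not reported here.

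Depth came from the whole reads recovered by multiplying with the size factors, 15158712 to 20079349 per library. The median half-width of the 95% interval of the log2 fold change was 0.254 over all tested genes, and the median SD within groups was 0.138. Chi-square per degree of freedom between libraries of the same group ran from 3.97 to 12.6 over the 6 pairs, above the 1 of counting noise. Pairs across the groups were not compared, and the values do not show that libraries came from separate tissue. In 5 simulated sets of libraries with 200 changed genes each, limma recovered 52.3% of genes changed 1.5-fold, 78.3% of those changed 2-fold and 96.0% of those changed 4-fold, with 13.6 false calls per set, against 14.2 with edgeR and 26.6 with DESeq2. A list shifted on purpose was called in 5 of the 5 sets, and 0 other lists were called. The simulation drew each gene independently, so the genes of a list shared no variation between libraries. The 0 therefore does not show how often camera calls lists falsely in these data. The 9 other splits of the real libraries into 3 and 3 called 3 to 18 lists.

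The settings fixed in this way were a pseudocount of 0.1 or 5, no filter, a floor of 50 in place of the planned 5 TPM, median-of-ratios and quantile scaling, scaling without mitochondrial-encoded genes, no trend and no robust moderation, library weights, the noradrenergic list mean as a covariate, and leaving out each library. Tests on the recovered reads with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, a floor of 1 and the cerebellar list mean as a covariate were added after seeing the data. All 6 library columns were used.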

Results

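The locus coeruleus, the pontine nucleus that supplies noradrenaline to most of the brain, was profiled by bulk poly-A RNA sequencing in wild-type (WT) mice and in 5xFAD mice. The 5xFAD line carries human APP with familial Alzheimer's disease mutations in a mouse Thy1 expression cassette and deposits amyloid in the brain. Punches of locus coeruleus tissue gave 3 WT libraries (numbered 62, 63 and 66) and 3 5xFAD libraries (64, 65 and 79). The series is concerned with tau phosphorylation, early sleep loss and overexcitable neurons in this nucleus, and the comparison asks which transcripts differed between the genotypes in the punched tissue. The WT libraries held 19343185, 20079349 and 17362733 reads assigned to genes, and the 5xFAD libraries held 15158712, 16483738 and 17774759. Between 22617 and 23565 genes had a value above 0 in each library. Log2 fold changes are 5xFAD over WT on the log2(normalized count + 1) scale, with n = 3 in each group.

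Thy1 (ENSMUSG00000032011.6), a surface glycoprotein of neurons whose regulatory sequence drives the 5xFAD transgenes, had a higher count in 5xFAD tissue. Gene totals do not separate reads of the transgene cassette, which carries Thy1 sequence, from those of the endogenous gene. Thy1 was the only one of 16411 tested genes past the threshold of the limma test. Its normalized count was 8607 ± 571 in WT and 20324 ± 2983 in 5xFAD (SD, n = 3 each), a 2.35-fold difference with a log2 fold change of 1.23 (SE 0.11, 95% interval 0.98 to 1.48, limma adjusted p = 0.0456). The WT libraries read 8755, 7976 and 9090 and the 5xFAD libraries read 21875, 16885 and 22211, so all 3 5xFAD libraries lay above all 3 WT libraries. App, the mouse amyloid precursor, read 28144, 27447 and 28890 in WT and 28370, 25781 and 29381 in 5xFAD, with a log2 fold change of −0.02 (SE 0.06, 95% interval −0.16 to 0.12). The sign of this small value turned under another scaling, to 0.0733 with quantile normalization. Mapt, which encodes tau, read 9923, 9255 and 8868 in WT and 9524, 9614 and 9808 in 5xFAD, with a log2 fold change of 0.05 (SE 0.06, 95% interval −0.08 to 0.17). The call for Thy1 ended without a filter on low values (adjusted p = 0.526) and without the variance trend and robust moderation (adjusted p = 0.532). It also ended without WT 62 (adjusted p = 0.404), WT 63 (adjusted p = 0.231), WT 66 (adjusted p = 0.145), 5xFAD 64 (adjusted p = 0.314) or 5xFAD 79 (adjusted p = 0.178), at log2 fold changes of 1.16 to 1.27.

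All 6 libraries carried Y-linked transcripts. Ddx3y, a Y-linked helicase, ranged from 1870 to 2081 normalized counts, and Xist, the transcript that coats the inactive X chromosome, from 1.04 to 6.13. The groups therefore held tissue of male expression pattern alone.

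**Figure D1:**
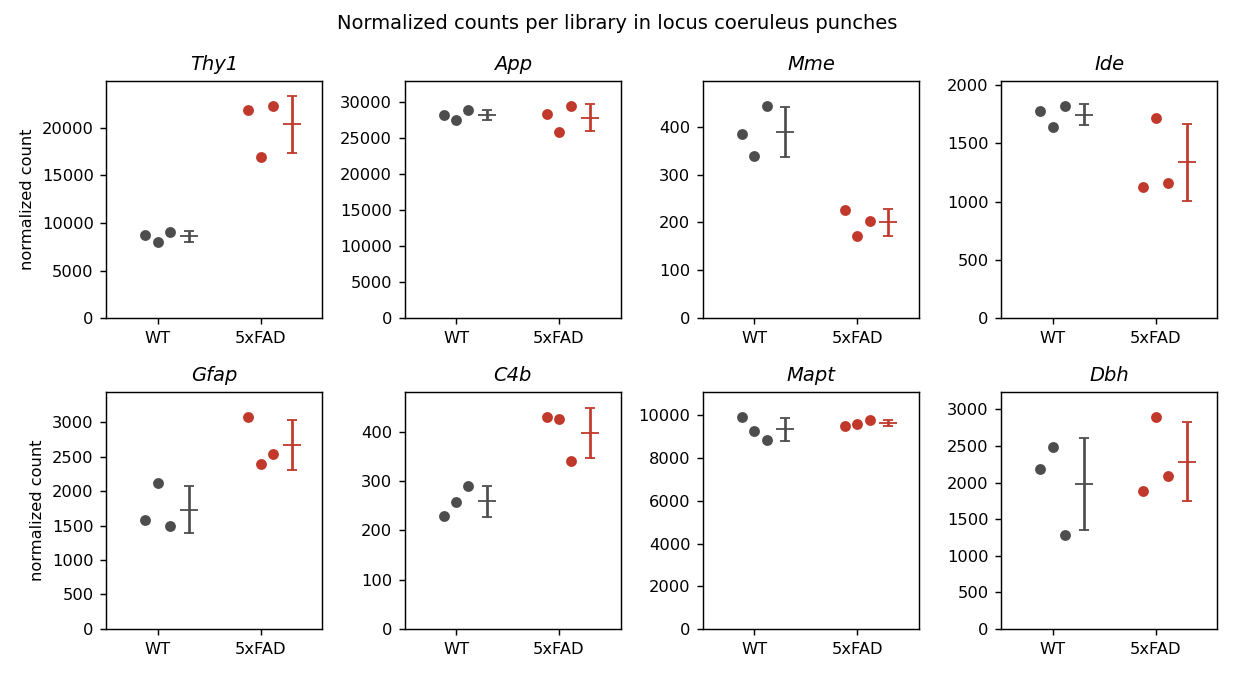
Normalized counts of single genes in each library of WT and 5xFAD locus coeruleus tissue, with 1 point per library and the mean and SD of each group of 3. Thy1 lies at 16885 to 22211 in 5xFAD against 7976 to 9090 in WT, and the Mme values of 172 to 226 in 5xFAD lie under all WT values of 338 to 442.

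Mme (ENSMUSG00000027820.13), which encodes neprilysin, a peptidase that degrades amyloid-beta, had the next smallest p. Its normalized count was 388 ± 52.1 in WT and 200.0 ± 27.5 in 5xFAD (SD, n = 3 each), a log2 fold change of −0.95 (SE 0.13, 95% interval −1.25 to −0.66) that did not pass in the limma test (adjusted p = 0.311). Gfap, the intermediate filament of reactive astrocytes, read 1728 ± 339 in WT and 2668 ± 358 in 5xFAD, a log2 fold change of 0.63 (SE 0.15). C4b, a complement component, read 259 ± 31.3 in WT and 398 ± 50.7 in 5xFAD, a log2 fold change of 0.62 (SE 0.12). Slc15a2, a peptide transporter, had a log2 fold change of 0.65 (SE 0.14), and Lum, a small proteoglycan of connective tissue, had one of 1.07 (SE 0.25). The remaining named genes with higher values had smaller differences, namely Lzts2 with a log2 fold change of 0.43 (SE 0.10), the acetyltransferase subunit Naa16 with 0.42 (SE 0.10), Prag1 with 0.38 (SE 0.10), Wiz with 0.35 (SE 0.08) and the synaptic scaffold Pick1 with 0.25 (SE 0.06).

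Among the genes with lower values, mt-Co2, a mitochondrial-encoded subunit of cytochrome c oxidase, read 8698 ± 1216 in WT and 6536 ± 515 in 5xFAD (SD, n = 3 each), a log2 fold change of −0.41 (SE 0.10). Gmps, an enzyme of guanine nucleotide synthesis, had a log2 fold change of −0.24 (SE 0.05), the glycerate kinase Glyctk one of −1.14 (SE 0.35) and the phospholipase Pafah2 one of −0.45 (SE 0.14). The others were Galntl6 with −0.40 (SE 0.12), the ciliary transport component Ift27 with −0.33 (SE 0.09), the cytokinesis regulator Racgap1 with −0.31 (SE 0.10), the ubiquitin ligase Lnx1 with −0.30 (SE 0.09) and Ndufb1-ps with −0.28 (SE 0.08). Mitochondrial transcripts share sequence with nuclear copies and Ndufb1-ps is annotated as a pseudogene, so the counts of both are uncertain. None of these genes other than Thy1 passed over all genes (limma adjusted p = 0.9995 for each except Mme).

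In total, limma called 1 gene higher and 0 lower, against 381 genes at an unadjusted p under 0.05, of which 209 had higher and 172 lower values. The edgeR test on recovered reads called Thy1 alone (adjusted p = 0.0216), with 380 genes at an unadjusted p under 0.05, and DESeq2 on the same reads called 2 genes higher and 1 lower. In simulated libraries with 200 changed genes per set, DESeq2 made 26.6 false calls per set, against 13.6 with limma. False calls under this adjustment depend on the number of changed genes, so these counts do not show whether the DESeq2 calls here are false. In the authors' deposited table, 3 of 28317 genes had an adjusted p under 0.05, Thy1 with a log2 fold change of 1.24 (adjusted p = 4.39e-29), Mme with −0.96 (adjusted p = 4.75e-05) and Gfap with 0.63 (adjusted p = 0.0244), as 5xFAD over WT. The groups of 3 did not overlap in 1217 tested genes, or 7.42%, against the 10% that chance gives. For 11716 genes, 71.4% of those tested, the 95% interval excluded a change of 1.5-fold or more in either direction.

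Genes next to Mme in the order of GENCODE M21 (GRCm38) were compared after its value was seen. Of the 20 nearest tested genes, 14 had lower and 6 had higher values in 5xFAD, and 6 had an unadjusted p under 0.05 where the rate over all genes gives 0.464. Those with lower values were Gmps, the purinergic receptor P2ry1 with a log2 fold change of −0.24 (SE 0.09), the exchange factor Arhgef26 with −0.20 (SE 0.08) and the orphan receptor Gpr149 with −0.61 (SE 0.27). Those with higher values were the vomeronasal receptor Vmn2r1 with a log2 fold change of 1.36 (SE 0.49) and the ADP-ribosyltransferase Tiparp with 0.28 (SE 0.13). None of the 20 passed over all genes in the limma test.

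**Figure D2:**
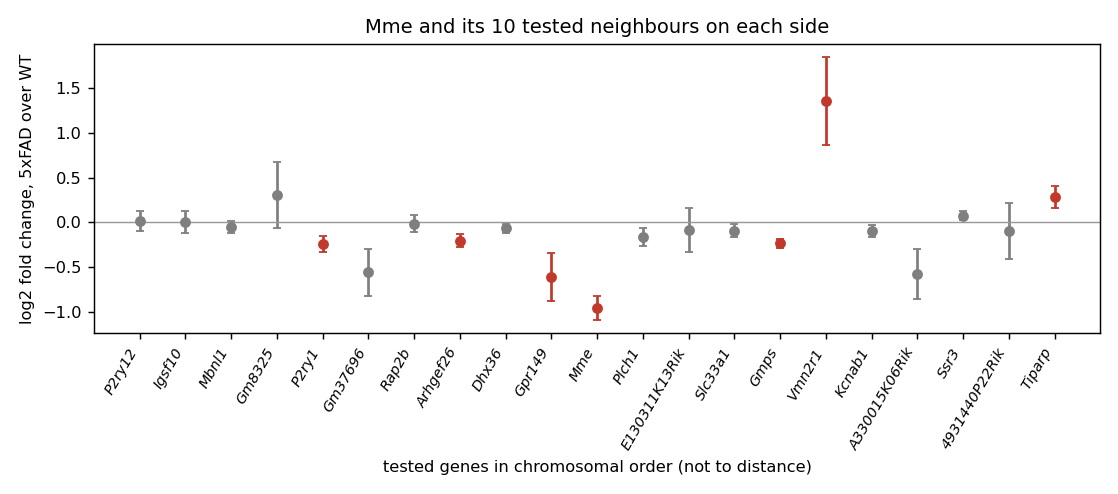
Log2 fold change (5xFAD over WT) with standard error of Mme and the 10 tested genes on each side of it, in the order of GENCODE M21 (GRCm38) and not drawn to distance, with genes at an unadjusted p under 0.05 in red. Mme lies at −0.95, and 14 of its 20 neighbours have values under 0.

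Of the noradrenergic identity genes, 18 of 19 were measured and had reads in every library, and none passed between the genotypes. The other, Hand1, named after its values were seen, was at 0 in all libraries. Dbh, which converts dopamine to noradrenaline, read 2187, 2492 and 1281 in WT and 1879, 2895 and 2090 in 5xFAD, with a log2 fold change of 0.23 (SE 0.31). Th, the rate-limiting enzyme of catecholamine synthesis, had a log2 fold change of 0.24 (SE 0.35), and Slc6a2, the noradrenaline transporter, one of 0.24 (SE 0.29). The homeobox factor Shox2 had a log2 fold change of −0.42 (SE 0.16) and the neurotrophic receptor Ret one of −0.19 (SE 0.11). Of 18 measured members 13 had higher and 5 lower values (camera adjusted p = 0.403), and 0 passed in the limma test, with 1 at an unadjusted p under 0.05. The mean log2 value of the list was 8.596, 8.76 and 8.02 in WT and 8.33, 8.72 and 8.55 in 5xFAD (two-sided exact permutation p = 0.9, where 3 against 3 allows no p under 0.1). The values of Dbh, Th and Slc6a2 turned to −0.0541, −0.0836 and −0.0425 without WT 66, and the 95% interval excluded a 1.5-fold change for 5 of the 18 members.

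Pan-neuronal genes and genes of synaptic vesicle release likewise did not pass the test as groups. Of 18 pan-neuronal genes 7 had higher and 11 lower values (camera adjusted p = 0.403), and Thy1 was the member past the threshold. Of 26 genes of vesicle release 12 had higher and 14 lower values (camera adjusted p = 0.403), and the 95% interval excluded a 1.5-fold change for all 26.

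Genes of disease-associated astrocytes, a reactive state described around amyloid plaques, rose as a group in 5xFAD in the camera test. Of 22 measured members 15 had higher and 7 lower values (camera adjusted p = 0.00416, and adjusted p = 0.710 with an estimated correlation). Gfap and C4b passed when adjusted over the list alone and not over all genes. The growth-factor binding protein Igfbp5 had a log2 fold change of 0.31 (SE 0.12) and the hyaluronan receptor Cd44 one of 0.50 (SE 0.22). The mean log2 value of the list was 9.42, 9.39 and 9.38 in WT and 9.53, 9.49 and 9.57 in 5xFAD, with no overlap between the groups (two-sided exact permutation p = 0.1, the smallest possible). The means of the circadian clock and cytosolic ribosomal lists did not overlap either (exact permutation p = 0.1 each). General astrocyte markers had 4 higher and 14 lower values of 18 (camera adjusted p = 0.216). The call for the disease-associated list ended without WT 63 (adjusted p = 0.0735) and without 5xFAD 79 (adjusted p = 0.0635).

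Microglial genes of the plaque response did not pass as a group. Of 24 measured members 12 had higher and 12 lower values (camera adjusted p = 0.741), among them Trem2, the lipid receptor that the response depends on, with a log2 fold change of 0.21 (SE 0.16), the receptor kinase Axl with −0.16 (SE 0.07) and the surface antigen Cd52 with −0.9996 (SE 0.35). The 5 members under the filter, chosen for mention after their values were seen, were close to 0 in both groups, with Cst7 at 0 to 2.08, Itgax at 0 to 11.2, Clec7a at 1.04 to 9.00, Ccl3 at 0 to 5.00 and Ccl4 at 0 to 1.86 normalized counts over the 6 libraries. Homeostatic microglial genes had 10 higher and 6 lower values of 16 (camera adjusted p = 0.327), including Olfml3 with a log2 fold change of 0.24 (SE 0.13), Tmem119 with 0.19 (SE 0.12) and the growth factor receptor Csf1r with 0.15 (SE 0.09). For 17 of the 24 plaque-response genes and 15 of the 16 homeostatic genes, the 95% interval excluded a 1.5-fold change.

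The plaque-induced gene network, a set of glial genes that rise near amyloid deposits, had 32 higher and 22 lower values of 54 (camera adjusted p = 0.268), and genes of complement and antigen presentation had 10 higher and 11 lower of 21 (camera adjusted p = 0.735). C4b passed in each when adjusted over the list alone. Interferon-response genes had 17 higher and 5 lower values of 22 (camera adjusted p = 0.107), with the transcription factor Irf7 at a log2 fold change of 0.90 (SE 0.25). Inflammatory mediators had 9 higher and 2 lower values of 11 (camera adjusted p = 0.107), with the pattern receptor Tlr2 at 0.41 (SE 0.24). Myelin and oligodendrocyte genes had 19 higher and 1 lower value of 20 (camera adjusted p = 0.107), with Mbp, the myelin basic protein gene, at 0.13 (SE 0.18), which turned to −0.0124 without 5xFAD 79. Oligodendrocyte precursor genes had 6 higher and 7 lower values of 13 (camera adjusted p = 0.998), with the growth factor receptor Pdgfra at 0.10 (SE 0.07). Endothelial and mural genes had 16 higher and 4 lower values of 20 (camera adjusted p = 0.0651), with the pericyte peptidase Anpep at 0.67 (SE 0.25).

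Transcripts of tau, its kinases and its phosphatases did not pass as a group, and their differences in the punched tissue as a whole were bounded closely. Of 40 measured genes 17 had higher and 23 lower values (camera adjusted p = 0.526), and the 95% interval excluded a 1.5-fold change for all 40. The stress kinase Mapk14 had a log2 fold change of 0.22 (SE 0.08), the neuronal kinase Mapk10 one of −0.14 (SE 0.06), and Cdk5r2, an activator of Cdk5, one of −0.10 (SE 0.06). These are transcript levels, and phosphorylation of tau was not analysed here. The punches mixed cell types, with myelin and cerebellar genes also read, so the bounds do not exclude a larger change confined to noradrenergic neurons.

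Genes of amyloid precursor processing and clearance had 16 higher and 11 lower values of 27 (camera adjusted p = 0.961), and Mme passed when adjusted over the list alone. Ide, the insulin-degrading enzyme, which also cleaves amyloid-beta, read 1775, 1642 and 1816 in WT and 1128, 1717 and 1163 in 5xFAD, with a log2 fold change of −0.41 (SE 0.16). Without 5xFAD 65 its log2 fold change was −0.61 and it passed over all genes (adjusted p = 0.0361). Psenen, a gamma-secretase subunit, had a log2 fold change of −0.14 (SE 0.07). The 95% interval excluded a 1.5-fold change for 24 of the 27 genes.

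Ion channel genes, which set the excitability of neurons, did not pass as groups. Voltage-gated potassium channel genes had 18 higher and 20 lower values of 38 (camera adjusted p = 0.541), with the auxiliary subunit Kcnab1 at a log2 fold change of −0.10 (SE 0.07). The other potassium channel genes had 18 higher and 10 lower values of 28 (camera adjusted p = 0.403), with Kcnmb4, an auxiliary subunit of large-conductance calcium-activated channels, at 0.60 (SE 0.26). Sodium, calcium and HCN channel genes had 19 higher and 17 lower values of 36 (camera adjusted p = 0.960), with the calcium channel subunit Cacna2d3 at a log2 fold change of −0.22 (SE 0.10). The limma test called 0 members of these lists, and 1 had an unadjusted p under 0.05. The 95% interval excluded a 1.5-fold change for 31 of 38, 24 of 28 and 27 of 36 genes in the 3 lists. These bounds hold for the mixed tissue of the punches and not for noradrenergic neurons alone.

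Genes of transmitter systems, the clock and neuronal activity did not pass as groups either. Genes of GABA and glycine transmission had 10 higher and 18 lower values of 28 (camera adjusted p = 0.268), with the receptor subunit Gabrg1 and the vesicular transporter Slc32a1 both at a log2 fold change of −0.13 (SE 0.06 each). Genes of glutamate transmission had 22 higher and 11 lower values of 33 (camera adjusted p = 0.308), with the vesicular transporter Slc17a8 at −0.49 (SE 0.19). Receptors for monoamines, orexin, adenosine and other modulators had 13 higher and 21 lower values of 34 (camera adjusted p = 0.269), with Adra2a, the inhibitory autoreceptor of noradrenergic neurons, at −0.22 (SE 0.09). Circadian clock genes had 11 higher and 9 lower values of 20 (camera adjusted p = 0.268), with the repressors Nfil3 at 0.29 (SE 0.13) and Per2 at 0.24 (SE 0.12). Immediate-early genes, which neuronal activity and tissue handling both induce, had 14 higher and 8 lower values of 22 (camera adjusted p = 0.144), with Jund at 0.19 (SE 0.07). The median, mean and test direction differed in sign among themselves for 10 lists, none of them past the threshold, which include plaque-response microglia, amyloid processing, voltage-gated potassium channels and GABA and glycine transmission.

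Genes of cerebellar neurons, whose tissue borders the punched area, rose as a group in the camera test, but their list means overlapped between genotypes. In the test, 21 of 21 members were higher in 5xFAD (camera adjusted p = 4.64e-09, and adjusted p = 0.717 with an estimated correlation). No member passed in the limma test, and 1 had an unadjusted p under 0.05. Gabra6, a receptor subunit of cerebellar granule cells, read 48.3, 1079 and 70.4 in WT and 817, 1402 and 341 in 5xFAD, a log2 fold change of 2.23 (SE 1.48). Cbln1, a synaptic organizer, had a log2 fold change of 0.27 (SE 0.10), and Eomes, a factor of unipolar brush cells, one of 1.28 (SE 0.66). The mean log2 value of the list was 7.64, 9.67 and 8.20 in WT and 9.38, 9.96 and 8.70 in 5xFAD, a difference of 0.84 within a range of 2.33 (two-sided exact permutation p = 0.3). The first principal component held 32.0% of the variance, of which genotype accounted for 6.73% (exact permutation p = 0.7). Its scores followed the cerebellar mean over the 6 libraries (Pearson r = 0.888, exact permutation p = 0.0292, Spearman rho = 0.829, exact permutation p = 0.0583, r = 0.882 without the 2 farthest libraries, the 1 relation computed). The component was computed over all tested genes, these 21 among them, and was not recomputed without them. The relation is therefore partly that of a part with its whole, and does not show that cerebellar content drives the component.

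**Figure D3:**
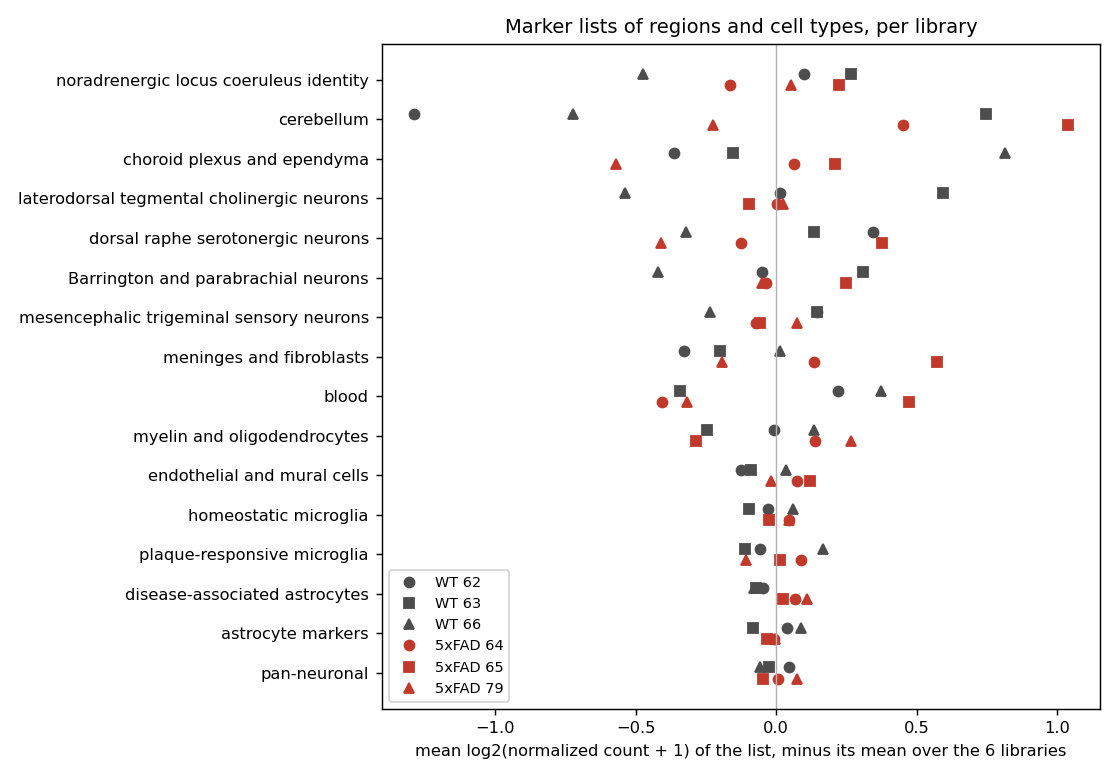
Mean log2(normalized count + 1) of marker lists in each of the 3 WT (grey) and 3 5xFAD (red) libraries, minus the list's mean over the 6 libraries, with 1 point per library. The cerebellar list has the widest range of those drawn, 2.33 with overlapping groups, and the disease-associated astrocyte list spans 0.190 with all 5xFAD libraries above all WT libraries.

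Genes of meninges and fibroblasts were higher as a group in 5xFAD in the camera test, with 12 of 14 members higher and 2 lower (camera adjusted p = 0.000161, and adjusted p = 0.715 with an estimated correlation). Lum passed when adjusted over the list alone, the collagen Col1a1 had a log2 fold change of 0.41 (SE 0.14) and Col3a1 one of 0.72 (SE 0.27). The mean log2 value of the list was 6.69, 6.83 and 7.04 in WT and 7.16, 7.60 and 6.83 in 5xFAD, so that 5xFAD 79 lay within the WT values (two-sided exact permutation p = 0.2). The endothelial and mural list ranked the 6 libraries in the same order, from 7.99 in WT 62 to 8.24 in 5xFAD 65, and the cerebellar list was also lowest in WT 62 and highest in 5xFAD 65, but second highest in WT 63.

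Genes of mitochondrial respiration fell as groups in the camera test, but their list means overlapped between the genotypes. The mitochondrial-encoded list mean was 15.35, 15.11 and 15.20 in WT and 15.13, 15.08 and 15.15 in 5xFAD (exact permutation p = 0.3). The nuclear-encoded list mean was 11.12, 11.02 and 11.18 in WT and 11.07, 10.98 and 11.08 in 5xFAD (exact permutation p = 0.4). Of 13 mitochondrial-encoded transcripts 12 were lower (camera adjusted p = 0.000262, and adjusted p = 0.715 with an estimated correlation), including mt-Co2, mt-Nd6 with a log2 fold change of −0.16 (SE 0.06) and mt-Nd4l with −0.15 (SE 0.06). All mitochondrial-encoded genes of the data, these 13 among them, took 8.41%, 7.54% and 8.21% of reads in WT and 7.66%, 7.68% and 7.58% in 5xFAD. Of 36 nuclear-encoded genes of oxidative phosphorylation 35 were lower (camera adjusted p = 8.08e-07, and adjusted p = 0.867 with an estimated correlation), by a median log2 fold change of −0.07, with Ndufb3 at −0.15 (SE 0.06) and Cox5b at −0.14 (SE 0.06). The 95% interval excluded a 1.5-fold change for all 36. The mean of the cerebellar list differed by 0.84 between the same groups, and with it as a covariate the call ended for both lists. The median log2 fold change went from −0.087 (SD over members 0.13) to −0.028 (SD 0.18) for the mitochondrial-encoded list (adjusted p = 0.0880), with 10 of 13 still lower, and from −0.069 (SD 0.044) to −0.013 (SD 0.051) for the nuclear-encoded list (adjusted p = 0.502), with 20 of 36 lower. With smaller medians and wider spread over members, the lists no longer passed, while mt-Co2 kept −0.32, mt-Nd6 −0.15 and mt-Nd4l −0.16. The mitochondrial-encoded call also ended without WT 62 (adjusted p = 0.0858).

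Cytosolic ribosomal protein genes, many of which have processed pseudogenes that make their counts uncertain, fell as a group in the camera test. Of these, 32 of 40 were lower and 8 higher (camera adjusted p = 0.0383, and adjusted p = 0.715 with an estimated correlation). The shift was small, with a median log2 fold change of −0.02, Rpl38 at −0.19 (SE 0.07) and Rpl30 at −0.09 (SE 0.05). The call ended without WT 62 (adjusted p = 0.0868), WT 66 (adjusted p = 0.0779), 5xFAD 64 (adjusted p = 0.0573), 5xFAD 65 (adjusted p = 0.179) or 5xFAD 79 (adjusted p = 0.0635), and with the cerebellar mean as a covariate (adjusted p = 0.223), where the median went from −0.022 (SD over members 0.045) to −0.014 (SD 0.054). Cholesterol synthesis genes had 12 higher and 7 lower values of 19 and did not pass (camera adjusted p = 0.0514), with the sterol carrier Stard4 at 0.15 (SE 0.05) and the mevalonate pathway enzyme Mvd at 0.32 (SE 0.13). None of the 6 lists past the threshold stayed past it with an estimated correlation or with fry.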

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

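The tests with edgeR, with DESeq2, with a floor of 1 normalized count and with the cerebellar mean as a covariate were chosen only after the results were seen. The log2 fold change of Thy1 stayed between 1.16 and 1.36 in all settings run, and its adjusted p ranged from 4.39e-29 (DESeq2) to 0.532. At an unchanged log2 fold change of 1.23 it did not pass without a filter (adjusted p = 0.526), without trend and robust moderation (adjusted p = 0.532) or with a floor of 1 (adjusted p = 0.0688). With a library left out, the log2 fold change ran from 1.16 to 1.36, and with fewer samples Thy1 passed only without 5xFAD 65 (adjusted p = 2.49e-05). The count of higher genes, 1 in the limma test, was 0 without a filter, without trend and robust moderation and with a floor of 1, 2 with DESeq2, and 0 to 1 with a library left out (0 without WT 62, WT 63, 5xFAD 64 or 5xFAD 79). The 1 gene without 5xFAD 65 was Thy1, and the 1 gene without WT 66 was not Thy1 but 2210418O10Rik (log2 fold change 2.43, adjusted p = 0.0309 in a range of 0.0309 to 1.00), chosen for mention after its values were seen. The count of lower genes, 0 in the limma test with 381 genes at an unadjusted p under 0.05 and 0 with edgeR, was 1 without a filter, with the noradrenergic covariate and with DESeq2, Mme in each, and 0 to 1 with a library left out (1 without 5xFAD 65, Ide). The adjusted p of Mme ranged from 4.75e-05 with DESeq2 to 1.00 with a library left out, through 0.00715 without a filter and 0.0391 with the noradrenergic covariate. Gfap passed only with DESeq2 (0.63, adjusted p = 0.0244, range 0.0244 to 1.00). The causes were not tested.

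App, near 0, changed sign, with 0.0733 under quantile normalization, 0.0298 with the cerebellar covariate and −0.058 to 0.0363 with a library left out. Dbh ran from −0.0541 to 0.43, Th from −0.0836 to 0.42 and Slc6a2 from −0.0425 to 0.43, each lowest without WT 66, and Mbp from −0.0124 (without 5xFAD 79) to 0.32.

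The count of higher lists, 3 with camera, was 5 with quantile normalization, 5 with library weights, 7 with the noradrenergic covariate, 10 with the cerebellar covariate, and 0 with an estimated correlation and 0 with fry. It was 3 to 10 with a library left out (5 without WT 63, 10 without WT 66, 6 without 5xFAD 65). The count of lower lists, 3 with camera, was 1 when scaled without mitochondrial-encoded genes, a setting that removes 1 of the 3 lists by construction, 5 with library weights, 0 with an estimated correlation and 0 with fry, and 2 to 6 with a library left out (6 without WT 63 or WT 66). The cerebellar list turned downward with its own mean as the covariate (adjusted p = 0.589), as that setting removes it by construction. Under the same covariate, the disease-associated astrocyte list kept its call (camera adjusted p = 0.000124), with its median log2 fold change going from 0.079 to 0.139. The meningeal list also kept its call (camera adjusted p = 0.0283), with its median going from 0.331 to 0.206. The mitochondrial-encoded, nuclear-encoded and ribosomal lists lost theirs. The ribosomal call also ended without a filter (adjusted p = 0.0706), with quantile normalization (adjusted p = 0.0946), when scaled without mitochondrial-encoded genes (adjusted p = 0.0936), without trend and robust moderation (adjusted p = 0.111) and with a floor of 1 (adjusted p = 0.0611), within a range of 0.0255 to 0.739. Other causes were not tested. Among genes and lists, 36 calls were lost (8 of Thy1, 28 of the 6 lists), 6 gained and 9 values changed sign. The 1538 others were mostly of genes never called.

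No paired analysis was possible because the 2 groups share no library numbers. Median-of-ratios scaling moved nothing, since the values were already scaled that way, and so says nothing about stability. The covariate for sex could not be fitted, as all libraries carried Y-linked transcripts, and edgeR without a filter was not run. Depth and the spread between libraries were not separated as limits on precision. In the mixed tissue of the punches, the 95% interval excluded a 1.5-fold change for 40 of 40 genes of tau and its kinases, 5 of 18 noradrenergic genes, 3 of 21 cerebellar genes, 3 of 11 measured inflammatory mediators and 0 of 5 blood genes.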

Other observations

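The tests on Thy1, the alignment test on Mme, the setting with the cerebellar mean as a covariate, and the comparison of the share of low p-values with the other splits were chosen only after the results were seen.

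Markers of nuclei and tissues around the locus coeruleus other than the cerebellum and the meninges varied between libraries, and none of the lists given here passed between the genotypes. Serotonergic genes of the dorsal raphe had 1 higher and 5 lower values of 6 (camera adjusted p = 0.539), and the mean log2 value of the list spanned 0.787 over the 6 libraries. Cholinergic genes of the laterodorsal tegmentum had 3 higher and 3 lower values of 6 (camera adjusted p = 0.961) and spanned 1.13, from 7.005 in WT 66 to 8.14 in WT 63. Sensory neuron genes of the mesencephalic trigeminal nucleus had 4 higher and 5 lower values of 9 (camera adjusted p = 0.961), and genes of Barrington's nucleus and the parabrachial complex had 9 higher and 3 lower of 12 (camera adjusted p = 0.332). Choroid plexus and ependymal genes had 1 higher and 11 lower values of 12 (camera adjusted p = 0.200) with a list mean of 7.40 in WT 66 against 6.01 to 6.79 in the other libraries. Haemoglobin and other blood genes had 0 higher and 5 lower values of 5 (camera adjusted p = 0.269) with a span of 0.881.

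Genes of the heat-shock and unfolded-protein responses, chaperones that stress induces, had 14 higher and 11 lower values of 25 (camera adjusted p = 0.904), yet their list mean was 11.18 in WT 62 and 11.14 in 5xFAD 79 against 10.58 to 10.78 in the other 4 libraries. Members of the disease-associated astrocyte list under the filter were scarce, with Steap4 at 0.929 to 6.998 and Cxcl10 at 0 to 4.00 normalized counts, both highest in 5xFAD 79, and Lcn2 at 12.9999 in WT 62 and 0 to 3.12 in the other libraries, and the cytokine Tnf was at 0 in all libraries. These 4 genes were chosen after their values were seen.

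Thy1 was higher in 5xFAD while the pan-neuronal list as a whole did not pass. A larger share of neurons in the 5xFAD punches is argued against by the median log2 fold change of the pan-neuronal list without Thy1, −0.052 (95% bootstrap limits −0.089 to 0.015), against 1.23 for Thy1. The bootstrap resampled genes with the libraries held fixed, so its limits do not measure the spread between libraries. A candidate explanation that stays open is that reads from the transgene cassette, which carries Thy1 sequence, were assigned to mouse Thy1, but gene totals do not separate exons, and App at −0.0182 shows only that human APP reads did not raise the mouse gene by more than its 95% limit of 0.12. A biological rise of endogenous Thy1 with genotype remains untested, so these cannot be told apart.

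Mme had a lower value in 5xFAD (limma adjusted p = 0.311), as had most of its 20 nearest tested neighbours, and none of these genes passed in the limma test. Different cerebellar or noradrenergic content is argued against, as Mme kept a log2 fold change of −0.84 with the cerebellar covariate. The upper 95% limits were −0.54 there and −0.69 with the noradrenergic covariate. Other dissection content was not fitted and stays open, such as that of choroid plexus and ependymal genes, whose list mean spanned 1.39. Among 15754 windows over the genome, the 20 neighbours of Mme lay at percentile 99.96 for their median absolute moderated statistic, 1.46 against 0.639 at the middle of all windows, and at 99.7 to 99.96 in the alternatives, which is consistent with a block of other alleles linked to the locus in the 5xFAD line. Fewer reads aligned from such an allele stays open, with 14 of 20 neighbours lower, and 4 lower and 2 higher at an unadjusted p under 0.05. An effect of amyloid on neprilysin transcription, with the genotype itself as the cause, is untested and stays open.

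The p-values of the genotype comparison were shifted towards 1, with 2.32% of genes at an unadjusted p under 0.05 and a median p of 0.536. Variation in dissection content that crosses the groups is a candidate explanation, as the share rose to 3.62% with the cerebellar covariate and stayed at 2.35% with the noradrenergic one, while a test too strict for these values stays open, as the 4.70% of unchanged simulated genes was above the bound set in advance, but that bound was wrong because the simulation draws each gene independently and holds no variation that genes share between libraries, while the 9 other splits of the real libraries gave 1.63% to 15.4%, 3 of them under the share of the genotype split. The split with 15.4% set WT 62, WT 66 and 5xFAD 79 against WT 63, 5xFAD 64 and 5xFAD 65, the 3 libraries with the lowest and the 3 with the highest cerebellar means, and called 57 genes, which points to a structure of the samples other than genotype. Of the 10 splits of the libraries into 3 and 3, 4 gave at least the 1 gene of the real split (highest other 57) and 8 gave at least its 6 lists (highest other 18), and 10 splits are too few for a share under 0.05. Without WT 63 the share at an unadjusted p under 0.05 was 6.02%, and with library weights 6.06%, and no biological explanation was tested.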
